A study of Rattus norvegicus with 23 samples.

How the data were processed

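Lung tissue of 23 rats was profiled by 3' mRNA sequencing, in which a library holds fragments from near the polyadenylated end of each transcript, so that reads count transcripts without a correction for gene length. Per the labels' protocols, the disease model combined monocrotaline (MCT), a plant alkaloid that injures the pulmonary vessels, given at day 0, with an aorto-caval shunt, a surgical connection that raises blood flow through the lung, made at day 7. Per the labels' protocols, lungs came from donor rats at day 14, 21 or 28, RNA was extracted from the right lung of each donor rat in 3 replicates of 500 ng, libraries were made with a QuantSeq forward kit and sequenced on 3 Illumina HiSeq lanes. The labels name the lobe in more than one way, as middle and as upper, and do not say which lane or preparation batch a library belonged to. One count table was given for each rat, and how its 3 extractions were combined is not given in the sources used here.

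The authors deposited 1 count table per library, with whole-number read counts for 32402 Ensembl rat gene IDs and 5 summary lines for reads that were not assigned to a gene. Per the submitters' processing notes, the tools involved were STAR, HTSeq, FastQC and DESeq2 and the genome build was Rnor_6.0. Versions, strand settings and the annotation release are not given in the sources used here. The counts were used as deposited, without the summary lines. The table of reversible replicate 2 is marked as corrected, and what was corrected is not given in the sources used here. Reads without a unique alignment made up 47.7% to 86.4% of the lines' total per library. Of the other reads, 41.2% to 53.3% overlapped no gene. Genes that share sequence with a close copy, that overlap another gene or that lie antisense to one may therefore be under-counted or hold reads of their neighbour.

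The tables hold no gene names, and the reference table of rat genes used here lists no Ensembl ID, so 0 of the 32402 IDs matched a symbol, a position or a length. The gene lists and key genes fixed before the data were examined (cell type markers, extracellular matrix, DNA damage and senescence, BMP signalling and others) could not be tested for this reason, and neither could list scores or checks of gene length and GC content. The rule for named genes asked for the largest rises and falls among genes with an adjusted p under 0.05 and an average log2 CPM of at least 1. Without names it was applied to IDs for the comparison of irreversible with reversible disease only, and 2 rising and 2 falling IDs are given.

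Groups were taken from each sample's own labels, which give 12 reversible, 6 irreversible and 5 control rats. The series' design text counts 11, 7 and 5. The labels put the control lungs at day 21, the reversible lungs at day 14 (4 rats), 21 (7 rats) and 27 (1 rat), and the irreversible lungs at day 21 (3 rats) and 28 (3 rats). Replicate names in the labels were not shared between groups, so no paired analysis was made. Pairs of libraries within a group were compared by a chi-square of their counts over IDs with at least 20 reads in the pair. The closest pair, control replicates A3 and B3, had a chi-square of 3.14 per degree of freedom, against 33.6 to 106 in the other control pairs. This is above counting noise, which argues against repeated counts of 1 library. It does not show whether they came from separate rats. The labels list them as separate samples and each was counted as 1 sample.

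Differential expression was tested in R 4.3.3 with edgeR 4.0.16, using the quasi-likelihood test with robust estimation, TMM normalization and the filterByExpr filter (minimum count 10, minimum total count 15). P-values were adjusted by the Benjamini-Hochberg method and called below 0.05. One fit with a mean per group over all 23 libraries tested 12700 IDs and served the 3 group comparisons. A second fit with a mean per group and day, without the reversible library of day 27, tested 12913 IDs and served the comparisons within a day or between days. Log2 fold changes are edgeR's, and each standard error is the fold change divided by the square root of its F statistic. CPM values are counts per 1000000 gene reads after TMM scaling, and the prior count for log2 values was 2. P-values measure the spread between rats of the same group. A difference between preparation batches, which the labels do not record, adds to that spread only where batches mix within a group. One that goes with the groups enters the fold changes, and the p-values do not allow for it.

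Measures of each library were compared between groups by exact two-sided permutation tests of the difference in means, adjusted by Benjamini-Hochberg over 18 tests. Correlations across libraries were tested with 100000 permutations, or with all orders where fewer than 10 libraries entered. Principal components were computed on log2 CPM without the most abundant gene ID. Because that ID's share of the reads parted the libraries, libraries above and below a share of 10% were also treated as separate sets, a choice made after the data were seen. This is a division of samples by a property of the libraries and not a group of the study.

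Alternatives fixed before the data were examined were relative log expression size factors, no filter on low counts, non-robust estimation, DESeq2 1.42.0, limma 3.58.1 with voom and quality weights per library, only the groups compared, only the day-21 libraries, day as a linear covariate, and leaving out each library in turn. Alternatives added after the data were seen were the low-share libraries alone, the same without the day-27 library, the share of the most abundant ID as a covariate, the library set as a term with and without day, the share of reads not uniquely aligned as a covariate, and removal of the most abundant ID. Comparisons that share control libraries were set against 20 simulated draws of unchanged groups and against 20 splits of the controls into separate parts. Each draw simulated every library, controls included, gene by gene and without library sets.

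Gene reads per library ranged from 4.33 to 9.99 M (1000000 reads). The precision this gave was tested on simulated counts with the real libraries' sizes and mean of each gene, 200 genes changed and no library sets. The percentages of false calls therefore do not cover a difference between library sets that goes with the groups. For irreversible against reversible lungs, 77% of simulated 2-fold changes and 96% of 4-fold changes were called, and 6.49% of the calls were false. The matching percentages were 81, 92 and 3.89 for reversible lungs against control and 72, 97 and 6.11 for irreversible lungs against control. Among the low-share libraries alone, irreversible against reversible lungs gave 53, 94 and 4.55. Between irreversible lungs of day 28 and day 21 they were 46, 87 and 5.67. Figures were drawn with matplotlib 3.10.9.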

Results

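The series addressed pulmonary arterial hypertension (PAH), a disease of raised pressure and remodelled vessels in the lung, in a rat model of MCT, shunt and haemodynamic unloading in which the disease was labelled reversible or irreversible. Right lung tissue of 12 rats with reversible PAH, 6 rats with irreversible PAH and 5 control rats was sequenced from the 3' end of messenger RNA. The number of reads assigned to genes was 6.97 ± 0.444 M reads (M, 1000000) in control lungs (SD, n = 5), 7.40 ± 1.40 M reads in reversible lungs (SD, n = 12) and 8.56 ± 1.09 M reads in irreversible lungs (SD, n = 6). Per the labels, all control lungs were taken at day 21. Reversible lungs were taken at day 14 (4 rats), day 21 (7 rats) and day 27 (1 rat), and irreversible lungs at day 21 (3 rats) and day 28 (3 rats), so that disease label and day overlapped only at day 21. Genes are given by Ensembl ID, since the tables carried no gene names.

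Before the groups were compared, the libraries were examined for differences that the groups do not define. A single gene ID was the most abundant across the series, and its share of gene reads was 5.47 ± 4.66% in control lungs (SD, n = 5), 10.8 ± 5.32% in reversible lungs (SD, n = 12) and 3.42 ± 1.69% in irreversible lungs (SD, n = 6). The difference between irreversible and reversible lungs was -7.42 percentage points (exact permutation test, two-sided, p = 0.00555, adjusted p = 0.0499 over 18 tests). The shares fell into 2 sets with no value between 6.63% and 12.4%. Of the 9 libraries in the high-share set, 8 were reversible and 1 was control replicate 20. The 14 libraries in the low-share set held all 6 irreversible lungs, 4 reversible lungs and 4 controls. At day 21 all 7 reversible lungs were high-share and all 3 irreversible lungs were low-share. Reads without a unique alignment made up 60.2 ± 8.94% of the total in reversible lungs (SD, n = 12), 51.4 ± 2.42% in irreversible lungs (SD, n = 6) and 53.3 ± 1.76% in controls (SD, n = 5).

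**Figure D1:**
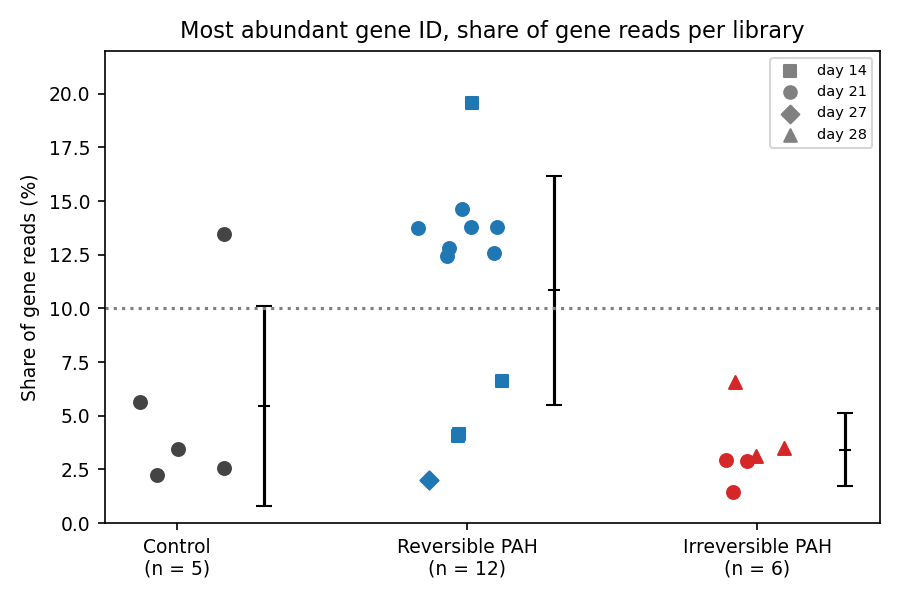
Share of gene reads (%) taken by the most abundant gene ID in each of the 23 libraries, by group, with markers for the day and a bar for the mean and SD of each group. Shares run from 1.47% to 6.63% in 14 libraries and from 12.4% to 19.6% in the other 9, with 10% drawn as a dotted line.

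The first principal component, computed without that gene ID, held 48.0% of the variance in log2 CPM and the second held 11.9%. Irreversible and reversible lungs differed along the first component (39.8 ± 26.1, SD, n = 6, against -21.5 ± 35.1, SD, n = 12; exact permutation test, two-sided, p = 0.00232, adjusted p = 0.0417 over 18 tests). Its score also followed the log2 share of the most abundant ID within the low-share set, with Pearson's r = -0.845 (permutation p = 0.00017, adjusted p = 0.00034 over 2 sets) and Spearman's rho = -0.780 (permutation p = 0.00173, adjusted p = 0.00346) over 14 libraries, and r = -0.791 without the 2 libraries farthest from the median share. Within the high-share set of 9 libraries r was -0.580 (exact permutation p = 0.0903) and rho was -0.617 (exact permutation p = 0.0857), and r was -0.312 without the 2 farthest libraries, so no relation was established there. Reversible replicate 12, the only library of day 27, had a score of 64.5, while the other 11 reversible lungs reached at most 12.4.

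**Figure D2:**
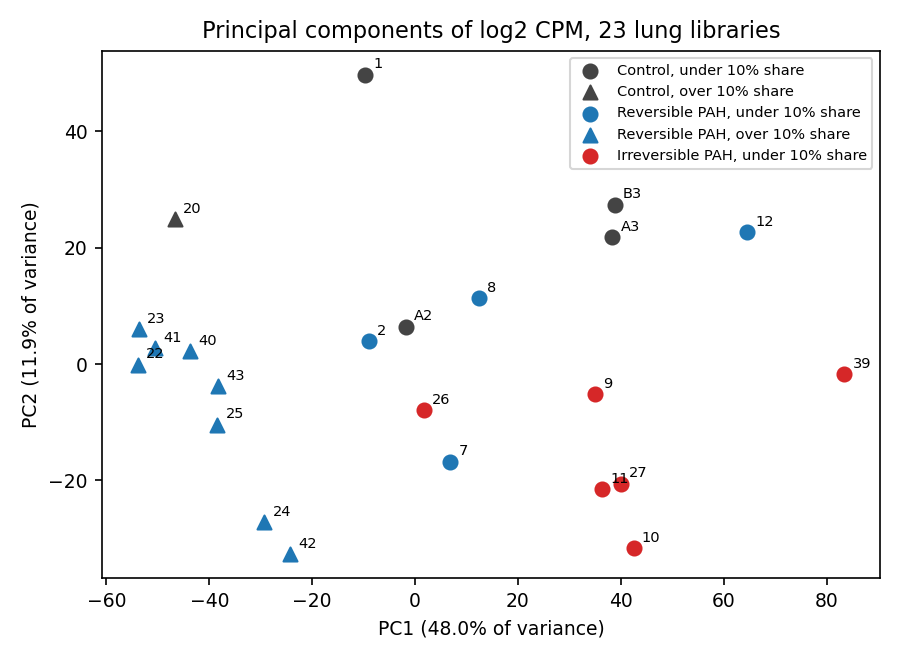
First and second principal components of log2 CPM for the 23 libraries, computed without the most abundant gene ID, with colour for the group, marker shape for the share of that ID and the replicate name beside each point. The 9 libraries over 10% share lie between -53.9 and -24.3 on the first component and the 14 others between -9.67 and 83.4.

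Reversible PAH was set against control to find what changed in lungs with the reversible form of the disease. In reversible lungs 488 gene IDs were higher and 384 were lower than in control lungs, 872 of 12700 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Rises were the larger changes, with 303 IDs at least 2-fold higher and 47 at least 2-fold lower, and the median absolute log2 fold change of the called IDs was 0.84. Among the low-share libraries alone (4 reversible and 4 control lungs) 273 IDs were higher and 91 lower. With the share of the most abundant ID as a covariate 1365 IDs were called. Without reversible replicate 12 the count in all libraries was 1447, against 506 without control replicate A3 and 532 without control replicate B3. Limma with quality weights called 7565 IDs, 4020 higher and 3545 lower. The balance turned to more falls than rises among the day-21 libraries alone (1057 higher and 1360 lower) and without reversible replicate 12 (665 higher and 782 lower).

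Irreversible PAH was set against the same controls. In irreversible lungs 700 gene IDs were higher and 562 were lower, 1262 of 12700 tested, with 359 at least 2-fold higher, 173 at least 2-fold lower and a median absolute log2 fold change of 0.89 among the called IDs (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). ENSRNOG00000053494 rose from 4.92 ± 3.84 CPM in control lungs (SD, n = 5) to 190 ± 116 CPM in irreversible lungs (SD, n = 6), a log2 fold change of 5.25 with a standard error of 0.73 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 8.59e-05). ENSRNOG00000024181 rose from 2.12 ± 0.877 CPM (SD, n = 5) to 89.5 ± 33.2 CPM (SD, n = 6), a log2 fold change of 5.38 with a standard error of 0.80 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000168). In reversible lungs these IDs stood at 15.5 ± 14.1 and 9.84 ± 11.7 CPM (SD, n = 12), and their log2 fold changes against control of 1.62 and 2.20 missed the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.118 and 0.0593). DESeq2 called both (Benjamini-Hochberg adjusted p = 0.0496 and 0.00923). Over the alternatives the adjusted p by edgeR, DESeq2 or limma ran from 0.0496 to 0.766 for ENSRNOG00000053494 and from 0.00923 to 0.545 for ENSRNOG00000024181. By edgeR, ENSRNOG00000024181 was also called in reversible lungs of day 21 alone, with the share of the most abundant ID as a covariate, with the library set as a term, and without reversible replicate 2, 8 or 40 (Benjamini-Hochberg adjusted p of 0.0167 to 0.0479). Among the low-share libraries 439 IDs were higher and 223 lower in irreversible lungs. In all libraries 2026 were called with the share as a covariate. The count in all libraries was 749 without control replicate 1, 738 without control replicate 20, 713 without irreversible replicate 10, 841 without irreversible replicate 11 and 2034 without irreversible replicate 26. Limma with quality weights called 3555 IDs and the day-21 libraries alone gave 2522. Falls outnumbered rises with quality weights (1649 higher and 1906 lower), with the share as a covariate (933 and 1093), and without irreversible replicate 26 (913 and 1121), control replicate A3 (637 and 717) or control replicate B3 (700 and 761).

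A part of the IDs was called against control in both conditions. Of the IDs called against control, 245 were higher in both reversible and irreversible lungs and 153 were lower in both, and 0 were called in opposite directions. Independent lists of these lengths would share 26.9 and 17.0 IDs. In 20 simulated draws of unchanged groups with common controls at most 0 called IDs were shared. These draws held no group difference and no library sets, so few calls were bound to arise in them. They do not show how many shared calls common controls and library sets could give. The 398 shared IDs had a median absolute log2 fold change of 0.92 in reversible and 1.09 in irreversible lungs. Their number was 258 without control replicate A2, 265 without control replicate A3, 775 with the share of the most abundant ID as a covariate and 2009 with limma and quality weights. When each comparison was given its own part of the controls, the IDs called the same way in both numbered 12 to 171 over 20 splits, with a median of 53. Among the low-share libraries 121 IDs were higher in both and 48 lower in both, against 9.66 and 1.64 for independent lists, and 0 were opposite. These comparisons also share their controls, and no draws or control splits were made for this set.

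A set of 147 IDs was called against control in the same direction in both conditions in all libraries, among the low-share libraries and with the share as a covariate. These fits reuse the same lungs and controls, so passing all of them is no independent support. No version with the controls split was made for this set, and its fold changes are those of IDs chosen by being called. Of these, 107 were higher, with a median log2 fold change of 1.47 in reversible and 1.64 in irreversible lungs, and 40 were lower, with medians of -0.91 and -0.97. Single IDs of the set reached log2 fold changes of 3.66 and -2.11 in reversible lungs and of 4.07 and -2.97 in irreversible lungs. Across all 12700 IDs the covariance of the log2 fold changes of both conditions against control was 0.102 and the correlation was 0.347, across genes, which are not independent replicates. Unchanged groups simulated with common controls and without library sets gave a covariance of 0.0486 and a correlation of 0.629. This left a difference in covariance of 0.0533. With the controls split the covariance averaged 0.0568 and ran from -0.179 to 0.166, so its sign depended on which controls went to which condition.

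The main question of the series was how irreversible differed from reversible disease. In irreversible lungs 1198 gene IDs were higher and 2564 were lower than in reversible lungs, 3762 of 12700 tested, with 109 at least 2-fold higher and 1186 at least 2-fold lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The largest rises were ENSRNOG00000053494, with a log2 fold change of 3.63 and a standard error of 0.47 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000293), and ENSRNOG00000024181, with 3.19 and 0.49 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000612). Each of these IDs was higher in every irreversible lung than in any reversible lung, at 87.6 CPM or more against at most 52.7 for the former and 53.04 CPM or more against at most 41.5 for the latter. Such a complete separation upward was seen for 37 IDs and downward for 13, where chance gives 0.00539% of IDs in each direction, or 0.684 of those tested. The chance value is an average, and since genes vary together a count can lie far from it by chance. Without reversible replicate 12 the numbers were 156 upward and 227 downward, so that 1 library set both the counts and their balance.

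Within the low-share libraries, where 6 irreversible and 4 reversible lungs could be compared, 35 IDs were called between the conditions, 29 of them higher and 6 lower in irreversible lungs, and 31 of the 35 were also called in the same direction over all libraries. In this set label and day did not overlap. The reversible lungs were of day 14 (3 rats) and day 27 (1 rat) and the irreversible lungs of day 21 and day 28. Over all diseased lungs 1 ID was called with library set and day as terms. Label, day and library set went largely together, so this fit could hardly part them. Its low count does not show that label had no effect. With the share of the most abundant ID as a covariate 33 were called, 25 higher and 8 lower, and 18 IDs were called in both ways. Across the 3762 IDs called over all libraries, the median log2 fold change in the called direction was 0.76 over all libraries, 0.34 in the low-share libraries and 0.24 with the covariate. Without reversible replicate 12 the low-share libraries gave 612 calls, all between lungs of day 14 and lungs of later days. Of these 258 were higher and 354 lower, so the balance turned to more falls than rises. The count in all libraries was 2493 without irreversible replicate 10, 2124 without irreversible replicate 39 and 5548 without reversible replicate 12. Limma with quality weights called 7342 IDs (3238 higher and 4104 lower), and in a fit of the day-21 libraries alone rises outnumbered falls (3199 and 2798).

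**Figure D3:**
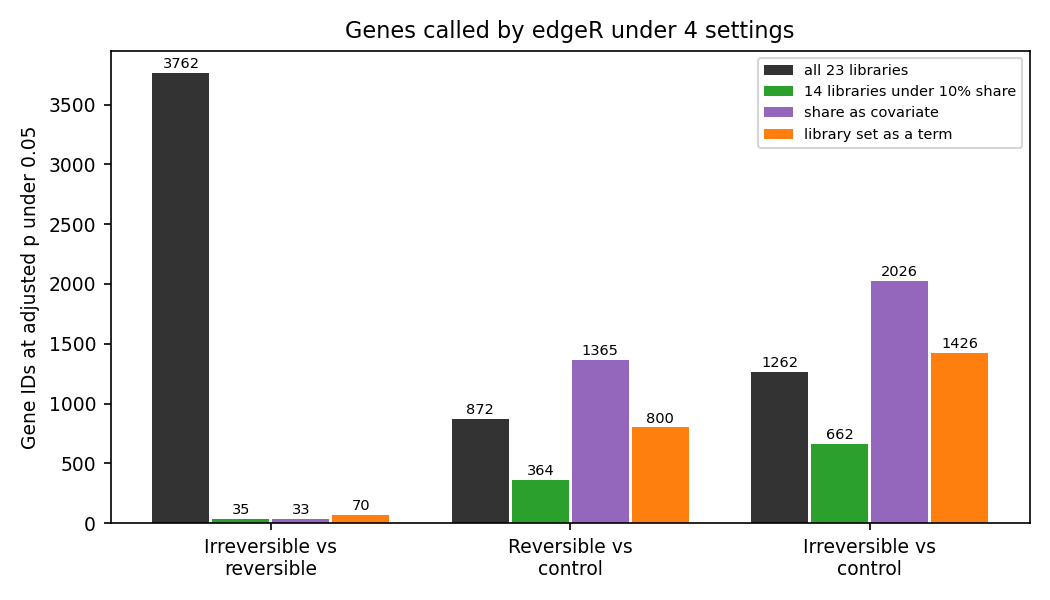
Number of gene IDs called by edgeR at an adjusted p under 0.05 in the 3 group comparisons, for all 23 libraries, for the 14 low-share libraries, with the share of the most abundant ID as a covariate and with the library set as a term. The bars for irreversible against reversible lungs stand at 3762, 35, 33 and 70, while those against control stand at 872, 364, 1365 and 800 for reversible lungs and at 1262, 662, 2026 and 1426 for irreversible lungs.

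The IDs that rose kept their direction within the low-share libraries, but their complete separation had fixed this. Each was higher in every irreversible lung than in any reversible lung, and all irreversible lungs were low-share. Their direction is thus no added support from the low-share libraries. ENSRNOG00000053494 had a log2 fold change of 4.03 there (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0119) and of 3.26 with the share as a covariate (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0548). ENSRNOG00000024181 had 2.78 and 2.48 and passed in neither (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.120 and 0.0752), and in the low-share libraries without reversible replicate 12 it had 4.50 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 7.54e-05). Over all alternatives that kept the full set of libraries or a named part of it, the adjusted p by edgeR, DESeq2 or limma ran from 1.35e-08 to 0.0913 for ENSRNOG00000053494 and from 2.91e-07 to 0.265 for ENSRNOG00000024181. The falls of the other 2 IDs were not called within the low-share libraries. ENSRNOG00000057270 stood at 27.3 ± 38.8 CPM in control (SD, n = 5), 70.4 ± 72.3 CPM in reversible (SD, n = 12) and 5.22 ± 4.08 CPM in irreversible lungs (SD, n = 6), a log2 fold change of -3.75 with a standard error of 0.86 between the conditions (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00889). It lay between 51.4 and 266 CPM in the high-share libraries, control replicate 20 with 96.2 CPM included, and its log2 fold change in the low-share libraries was -0.74 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.549). ENSRNOG00000008176 had a log2 fold change of -4.21 with a standard error of 1.60 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0495), which rested on reversible replicate 42 at 311 CPM. Without that library the log2 fold change was -1.18 and was not called (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.396). Over the alternatives the adjusted p ran from 2.21e-05 to 0.998 for ENSRNOG00000057270 and from 0.0354 to 0.994 for ENSRNOG00000008176 by edgeR, DESeq2 or limma.

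**Figure D4:**
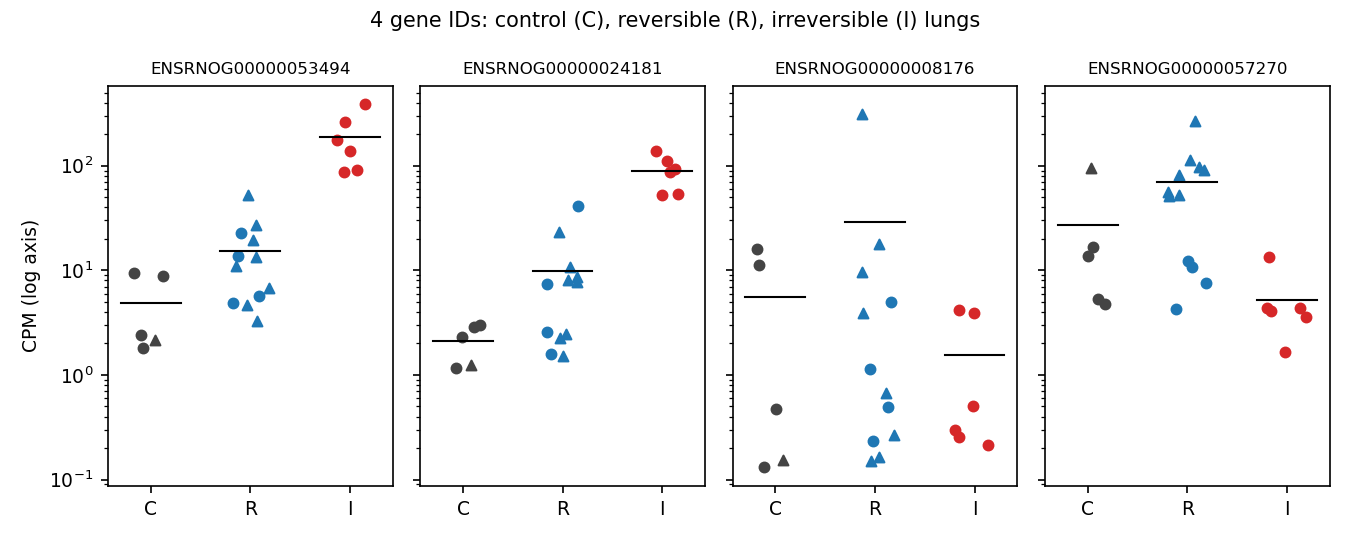
CPM on a log axis of the 4 named gene IDs in each library of control (C), reversible (R) and irreversible (I) lungs, with circles for low-share and triangles for high-share libraries and a line for the mean of each group. ENSRNOG00000053494 lies at 87.6 CPM or above in all irreversible lungs and at 52.7 CPM or below in all others, while ENSRNOG00000008176 lies at 311 CPM in reversible replicate 42 alone.

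At day 21, the day shared by both conditions, 2708 gene IDs were higher and 3323 were lower in 3 irreversible than in 7 reversible lungs, 6031 of 12913 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes numbered 424 upward and 1970 downward. Without irreversible replicate 39 the count was 3675. Rises outnumbered falls with the most abundant ID removed (3373 higher and 3104 lower) and without irreversible replicate 10 (2996 and 2900). They also did so without reversible replicate 23, 25, 40, 41 or 43. Falls stayed more numerous without irreversible replicate 9 or 39 or reversible replicate 24 or 42, so the balance was not settled. Among the diseased lungs of this day library set and disease label could not be told apart. A term for the library set would rest on other groups of the fit, and none was fitted. With the share of the most abundant ID as a covariate edgeR called 0 IDs, and with the share of reads not uniquely aligned it called 4595. Against the controls of the same day, 2466 IDs were called in reversible and 3016 in irreversible lungs. Against these day-21 controls 745 IDs were called in reversible lungs of day 14 and 676 in irreversible lungs of day 28.

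Within reversible disease, 205 IDs were higher and 467 were lower in 7 lungs of day 21 than in 4 lungs of day 14, 672 of 12913 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). All 7 lungs of day 21 were high-share and 3 of the 4 of day 14 were low-share. By edgeR 148 IDs were called with the share as a covariate. The exception, reversible replicate 22, had the lowest depth of the series at 4.33 M gene reads. Without it 2709 IDs were called, against 350, 116, 106 and 342 without reversible replicates 2, 7, 8 and 42. Rises outnumbered falls with limma and quality weights (2633 higher and 1517 lower) and with the share of reads not uniquely aligned as a covariate (1619 higher and 936 lower). Within irreversible disease, 0 IDs were called between 3 lungs of day 28 and 3 of day 21 by edgeR, with 1248 at an unadjusted p under 0.05, while DESeq2 called 19 and limma with quality weights 1. Without irreversible replicate 9 edgeR called 15 IDs, and without irreversible replicate 39 it called 1. The difference between both day effects, tested in the same fit, gave 0 IDs (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05).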

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

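The tests of disease label among the low-share libraries and of the depth of the day-27 library were chosen after their results had been seen, as were the fits on the low-share libraries, with the share of the most abundant ID and with that ID removed.

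Reversible replicate 22 stood apart from the other 3 reversible lungs of day 14 in several measures. Its reads without a unique alignment made up 86.4% of the total, against 57.9% in the nearest library and 56.1% in the highest control, and 8 reversible but 0 irreversible libraries lay above all controls in this measure. The most abundant gene ID took 19.6% of its gene reads, against 6.63% in the nearest library, and ENSRNOG00000057270 reached a log2 CPM of 8.06 there, against 3.65 in the nearest. The nearest libraries were low-share, while reversible replicate 22 was high-share. In the other high-share libraries the shares were 12.4% to 14.6%, and ENSRNOG00000057270 lay between 51.4 and 114 CPM, against 266 CPM here. Part of these gaps thus goes with the library set. Reversible replicate 40 had reads in 17582 gene IDs, against 16729 in the nearest of the other reversible lungs of day 21. These 4 outlying values came from 44 groups of values, and chance alone gives about 1 in 20.

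The 3762 calls between irreversible and reversible lungs went with the division into high-share and low-share libraries. With the most abundant ID removed 3871 genes were called. TMM scaling in the main fit already allows for a single abundant ID, so this count was bound to change little. It does not decide whether loss of reads to that ID was the source of the 3762 calls. A difference between library sets other than disease may account for many of them. Control replicate 20, the 1 high-share control, differed from the other controls along the same genes as high-share from low-share reversible lungs (r = 0.754 across genes). The same correlation ran from -0.732 to 0.263 for the other controls. These values are no separate support, since the mean each was set against held control replicate 20 and differences between controls cancel out. Disease label among the low-share libraries gave 35 calls, but 612 without reversible replicate 12, and label and day do not overlap in that set, so how much of the difference belongs to disease stays open. Day is argued against as the whole source, since 2552 genes were called with day as a linear covariate and 5997 among the lungs of day 21 alone. Neither fit allowed for library set, so day may still account for what library set does not. With library set and day as terms 1 gene was called, but label, day and library set went largely together. Tissue makeup and preparation batch remain untested, since the labels record no batch.

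Reversible replicate 12, the only lung of day 27, lay at 1.18 on an axis running from the other low-share reversible lungs (mean 0) to the irreversible lungs (mean 1), with 500 genes chosen without it. The irreversible lungs ran from 0.707 to 1.24 and the other low-share reversible lungs from -0.0253 to 0.175. The high-share reversible lungs, mostly of day 21, ran from 0.0638 to 0.665. The control lungs also lay between 0.600 and 0.859, so the axis is not one of disease severity. Low depth is argued against, since the library had 8.03 M gene reads (M, 1000000), inside the range of the other low-share libraries. A wrong label could place it there, and the series' design text counts 11 reversible and 7 irreversible rats where the labels count 12 and 6. Both rising gene IDs lay lower in this library than in every irreversible lung. ENSRNOG00000053494 stood at 22.9 CPM against 87.6 CPM or more. ENSRNOG00000024181 stood at 41.5 CPM against 53.04 CPM or more, with at most 23.3 CPM in the other reversible lungs. These are top genes in a single library. They were picked as the largest rises with this library counted as reversible, so they do not weigh against a wrong label. The late day points the same way as a wrong label would, so the explanations cannot be told apart here.

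Chance division of the libraries was examined with other splits into groups of the same sizes. For irreversible against reversible lungs 2 of 100 splits, the real one included, gave as many calls, so chance was excluded at a share of 5%, but the highest other split gave 5271 against the real 3762. That split had 0 high-share libraries on one side and 8 on the other, as the real one had, which points to the structure of the library sets, and 35 were called within the low-share set. For reversible lungs against control only the real split of 100 gave as many as 872, with 470 in the highest other, so chance was excluded at a share of 5%. Both of these splits had 8 high-share libraries on one side and 1 on the other, so the library sets were not excluded. For irreversible lungs against control 2 of 100 splits, the real one included, gave as many as 1262. This is under the 5% share, but the highest other split gave 1938. That split had a mean share of the most abundant ID of 2.76% on one side and 6.27% on the other. A division not made by label, with low shares on one side, thus gave more calls than the real one. At day 21 the real 6031 stood alone among 100 splits with 1339 in the highest other, as did the real 672 between reversible lungs of day 21 and day 14 with 145 in the highest other, which excludes chance but not the library sets. Between irreversible lungs of day 28 and day 21 all 10 splits gave 0 calls, like the real one, and 10 splits are too few for a share under 0.05.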

How the results depend on the processing

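Alternatives that use the low-share libraries, a share as a covariate, the library set as a term or removal of the most abundant ID were chosen after the results had been seen and the others were set before the data were examined. Size factors, non-robust estimation, removal of the most abundant ID and, in the group comparisons, the filter, DESeq2 and a fit of only the groups compared moved no count by more than 1.5 times, except for the calls between days given below. Day as a linear covariate gave 2552 calls between irreversible and reversible lungs. The covariance of the fold changes against control stayed between 0.0779 and 0.132 with a library left out and averaged 0.0568 with the controls split, and was 0.192 in the low-share libraries and 0.184 with the share of the most abundant ID as a covariate, against 0.102. Tests of gene lists, list scores and key genes were planned and not run, since no ID had a name. The cause of the changes below was not tested. Where fewer libraries entered a fit, lower power was not told apart from the removal of particular libraries.

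Irreversible against reversible lungs (3762) gave 7342 calls with limma and quality weights, 33 with the share of the most abundant ID and 83 with the share of reads not uniquely aligned as a covariate, 35 in the low-share libraries, 612 in these without day 27, 70 with the library set, 1 with library set and day, 5997 at day 21 alone, and 2124 (without irreversible replicate 39) to 5548 (without reversible replicate 12) with a library left out. In the same order of settings, reversible lungs against control (872) gave 7565 with quality weights, 1365 with the share, 364 in the low-share libraries, 504 in these without day 27, 2417 at day 21 alone and 506 (without control replicate A3) to 1447 (without reversible replicate 12). Irreversible lungs against control (1262) gave 3555 with quality weights, 2026 with the share, 662 in the low-share libraries, 2522 at day 21 alone and 713 (without irreversible replicate 10) to 2034 (without irreversible replicate 26). Calls in the same direction in both (398) numbered 2009 with quality weights, 775 with the share, 169 in the low-share libraries and 258 (without control replicate A2) to 550 (without reversible replicate 12).

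At day 21, irreversible against reversible lungs (6031) gave 0 calls by edgeR with the share as a covariate and 3675 (without irreversible replicate 39) to 6081 (without irreversible replicate 9). Reversible lungs of day 21 against day 14 (672) gave 445 without the filter, 1283 with DESeq2, 4150 with quality weights, 148 with the share, 2555 with the share of reads not uniquely aligned, and 106 (without reversible replicate 8) to 2709 (without reversible replicate 22). Irreversible lungs of day 28 against day 21 gave 19 with DESeq2, 1 with quality weights, and 0 to 15 (without irreversible replicate 9). At this depth and number of rats 46% of simulated 2-fold and 87% of 4-fold changes were recovered for the last comparison.

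With a library left out in turn, ENSRNOG00000053494, ENSRNOG00000024181 and ENSRNOG00000057270 stayed called between irreversible and reversible lungs, while ENSRNOG00000008176 was lost in 11 of 18 fits. Its log2 fold change between irreversible and reversible lungs turned to 0.13 with library set and day as terms. Its value for reversible lungs against control (2.38, not called) turned to -0.70 with DESeq2, -1.74 with quality weights, -1.95 in the low-share libraries, -1.77 in these without day 27 and -0.79 with the library set, and ran from -0.64 (without reversible replicate 42) to 3.23 with a library left out. For ENSRNOG00000057270 the value for reversible lungs against control (1.36, not called) turned to -0.34 with the share as a covariate, -0.18 in the low-share libraries and -0.10 with the library set, while it was called with limma and quality weights (3.26, Benjamini-Hochberg adjusted p = 6.5e-05) and by edgeR without control replicate 20 (2.80, Benjamini-Hochberg adjusted p = 0.0404).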

Other observations

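The counts of gene IDs that fully separated the groups were chosen after the results had been seen, and the test of a graded response was set beforehand.

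Separation of whole groups gave another view of the genes that set irreversible lungs apart. Over all 12 reversible lungs, 37 gene IDs were higher and 13 were lower in each of the 6 irreversible lungs than in any reversible lung, where chance gives 0.684 in each direction. Without reversible replicate 12, which was known to lie near the irreversible lungs, the numbers were 156 and 227, with no chance value that would apply. Against the 4 low-share reversible lungs alone, 190 were higher and 116 lower, where chance gives 0.476% of IDs in each direction, or 60.5. Label and day did not overlap among these lungs. The chance values are averages over divisions of the lungs. Genes vary together, so a count can lie far from such an average by chance. The reads of ENSRNOG00000024181 in reversible replicate 12, 41.5 CPM, lay between those of the other reversible lungs, at most 23.3 CPM, and the lowest irreversible lung, 53.04 CPM, whereas ENSRNOG00000053494 stood there at 22.9 CPM, below the 52.7 CPM of reversible replicate 25.

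A hypothesis was that irreversible lungs lie further from control along the response to disease. For each lung a score was taken as the mean difference in log2 CPM from the control mean, signed by direction, over the genes called between all diseased lungs and control. Scores were 1.22 ± 0.0864 in irreversible (SD, n = 6) and 1.09 ± 0.152 in reversible lungs (SD, n = 4) of the low-share set over 468 genes, a difference of 0.128 (exact permutation test, two-sided, p = 0.143). Over all libraries the difference was -0.0351 (exact permutation test, p = 0.630; n = 6 and n = 12; 769 genes), and in the low-share set without the day-27 library it was -0.0119 (exact permutation test, p = 0.917; n = 6 and n = 3; 604 genes). The hypothesis may hold or not: the sign of the difference depended on the libraries, and no difference was detected with these numbers of rats.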
